A study of Mus musculus with 12 samples.

How the data were processed

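Mammary tissue of 12 mice, 3 of each of 4 genotypes, was hybridized to Affymetrix whole-genome mouse arrays as biotin-labelled cRNA made from total RNA extracted with Trizol, per the labels. The values deposited by the authors are log2 signals per probe set. The submitters' processing notes name RMA and Partek, and versions and settings are not given in the sources used here. Array medians of the deposited probe set values differed, so these values do not share 1 common distribution. Whether signals were normalized between arrays before they were summarized per probe set cannot be read from this. The sample descriptions in the labels speak of sorted cells, and the treatment text of an injection of PolyIC that induces Mx1-Cre in blood-forming tissue. The series design gives whole mammary tissue, and the design was followed. Whether these mice were injected is not settled by the labels, and any bearing of it on interferon response genes was not tested. Sample titles were not used to set groups: they hold the letters ABB for the arrays labelled Stat5a-/- and AAB for those labelled Stat5ab+/null, and if the letters count intact alleles they disagree with the allele numbers in the genotype labels. Replicates were numbered in the order of the records.

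Genotypes were taken from the labels and the intact alleles of each gene were counted from them. Probe sets were matched to gene symbols with the platform's annotation table. In it, 34958 probe sets named 1 gene, 932 named several, 9160 other than controls named none, and 64 were controls. Probe sets with a mean below the 30th percentile (log2 6.04) were left out, and for each gene the probe set with the highest mean over the 12 arrays was used, which left 14198 genes. Beside a gene's value, another probe set past the filter is named where it points the other way in that comparison. Chromosomes and gene order came from a mouse gene table, and since no genome build is named for the arrays, coordinates are not given. A microRNA symbol among the largest falls was not reported, since its probe set was not matched to the microRNA itself. Genes named on the lists without a probe set past the filter were not analysed here.

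Comparisons were fitted with limma 3.58.1 in R 4.3.3: 1 mean per genotype, 1 spread shared by the 12 arrays, moderated statistics with 2-sided tests, and Benjamini-Hochberg adjustment over genes, with a call at an adjusted p under 0.05. The comparisons were single-Stat5a minus Stat5ab+/null, single-Stat5b minus Stat5ab+/null, single-Stat5b minus single-Stat5a, Stat5a-/- minus Stat5ab+/null, single-Stat5b minus Stat5a-/-, the difference of the third and the fourth (interaction), their mean (isoform average), and a moderated F test over the 4 genotypes. With 3 arrays against 3, an exact permutation test cannot go below p = 0.1. The interval and exact permutation p of the mean Stat5a and Stat5b signal between Stat5a-/- and Stat5ab+/null were computed per gene.

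Before the data were examined, 22 lists with 339 genes were fixed: milk proteins, secretory differentiation, lipid synthesis, Stat5 and cytokine targets, hormone-sensing luminal, alveolar luminal progenitor, luminal epithelium, basal epithelium, cell cycle, white and brown adipocytes, T cells, B and plasma cells, macrophages, endothelium, fibroblast matrix, skeletal muscle, nerve, skin keratinocytes, interferon response, circadian clock and immediate early genes. Some genes stand on several lists. Lists with at least 5 measured genes were tested with camera in limma (preset correlation 0.01, adjusted over lists), with an estimated correlation and with fry. The skin list had 4 of 10 genes measured and was not tested.

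The genes named were chosen by a rule fixed at the same time: Stat5a and Stat5b; in each comparison the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, or the 5 largest of each for the interaction and the isoform average; the 4 members of each called list with the largest change in its direction; the 4 milk protein genes and 4 Stat5 targets with the largest change; and up to 4 called members of each list. In the comparisons that cross the array sets a few of these are named. The same step fixed the tests and these alternatives: no filter, a filter at the 50th percentile, quantile normalization, centring of each array on its median, the mean of a gene's probe sets, every probe set, a trended robust variance, no moderation, array weights, a fit of only the groups compared, a 1.5-fold minimum, an adjusted p under 0.01, each array left out in turn, and for lists the estimated correlation and fry. After the data were seen, 3 more were added: the B cell and muscle list means of each array as covariates, 4 arrays left out together (Stat5a-/- 3, Stat5ab+/null 2, single-Stat5a 2 and single-Stat5b 2), and the 3' minus 5' control signal as a covariate. Comparisons of pairs of probe sets, spike-in controls, calls by chromosome and the genes next to Stat5a were also chosen after seeing the data.

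The procedure was tested on simulated data with the same arrays per group. With 50 genes changed at each size between single-Stat5b and single-Stat5a, 24 were called at 1 log2 unit, 47 at 2, 49 at 3 and 50 at 4, with 10 false calls among 180. With no change planted it called 0 genes in any of 7 comparisons or the F test, and a planted list was the 1 list called by camera and by fry. Each simulated gene was drawn independently, with 1 spread for all genotypes. The simulation therefore does not cover correlated genes or unequal spread, and its error rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.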

Results

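Transcript levels were measured by array in mammary tissue of 12 mice of 4 genotypes, 3 mice each, collected 6 days after a mating plug was seen, in early pregnancy. The genotypes differ in the number of intact alleles of Stat5a and Stat5b, neighbouring genes on chromosome 11 for the transcription factors that carry the prolactin signal in mammary epithelium. Stat5a-/- mice had 0 Stat5a and 2 Stat5b alleles, and Stat5ab+/null mice had 1 of each. Single-Stat5a mice kept 1 Stat5a allele and no intact Stat5b, and single-Stat5b mice kept 1 Stat5b allele and no intact Stat5a. The background was a mix of C57BL/6, FVB and 129. No wild-type mice were analysed here, so each difference lies between mutant genotypes. After a filter on low signal, 14198 genes were tested. The number of arrays, 3 per genotype, limits the precision. The labels do not say how far beyond being separate mice the samples are independent. Each limma p-value sets a difference against a spread pooled over the 4 genotypes of these samples. That spread was not equal: Pearson r between arrays was 0.957 to 0.973 within single-Stat5b and 0.985 to 0.989 within Stat5ab+/null. The pooled spread can be too small for comparisons with single-Stat5b and too large for Stat5a-/- against Stat5ab+/null.

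The targeted genes were read from 4 probe sets. The Stat5a probe set with the higher signal stood at 12.21 ± 0.34 (SD, n = 3) in single-Stat5a, 10.98 ± 0.11 in single-Stat5b, 10.30 ± 0.18 in Stat5a-/- and 9.91 ± 0.15 in Stat5ab+/null. In the same order of groups, the other Stat5a probe set stood at 5.29 ± 0.35, 5.05 ± 0.08, 8.94 ± 0.34 and 8.37 ± 0.40. The Stat5b probe sets stood at 9.43 ± 0.25, 9.63 ± 0.27, 9.59 ± 0.07 and 9.90 ± 0.07 for the one with the higher signal and at 6.15 ± 0.14, 6.79 ± 0.16, 8.27 ± 0.09 and 8.52 ± 0.18 for the other. Between single-Stat5b and single-Stat5a, the first Stat5a probe set fell by 1.23 on the log2 scale (limma adjusted p = 0.00286 over genes), a call lost with the mean of the probe sets (-0.74, adjusted p = 0.0954) and in a fit of these groups alone (0.0530), while the other differed by -0.24 and did not pass. The Stat5b probe sets differed by 0.64 (adjusted p = 0.0539 over all probe sets) and 0.20, higher where Stat5b was kept, and neither passed. Between Stat5a-/- and Stat5ab+/null, Stat5a differed by 0.39 and 0.56 and Stat5b by -0.25 and -0.31. All 4 of these differences run against the allele numbers in the labels and none passed, and the group is therefore called the arrays labelled Stat5a-/- below. Where the probes lie relative to the deleted parts of the genes is not given in the sources used here, and a probe outside a deleted part does not test the label. The titles of these arrays hold the letters ABB for Stat5a-/- and AAB for Stat5ab+/null. If the letters count intact alleles, each group would hold 3 rather than 2, and the arrays labelled Stat5a-/- would keep 1 Stat5a allele. They would still have fewer Stat5a and more Stat5b alleles than the other group, as in the labels. Genotypes and allele totals are given as labelled.

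**Figure D1:**
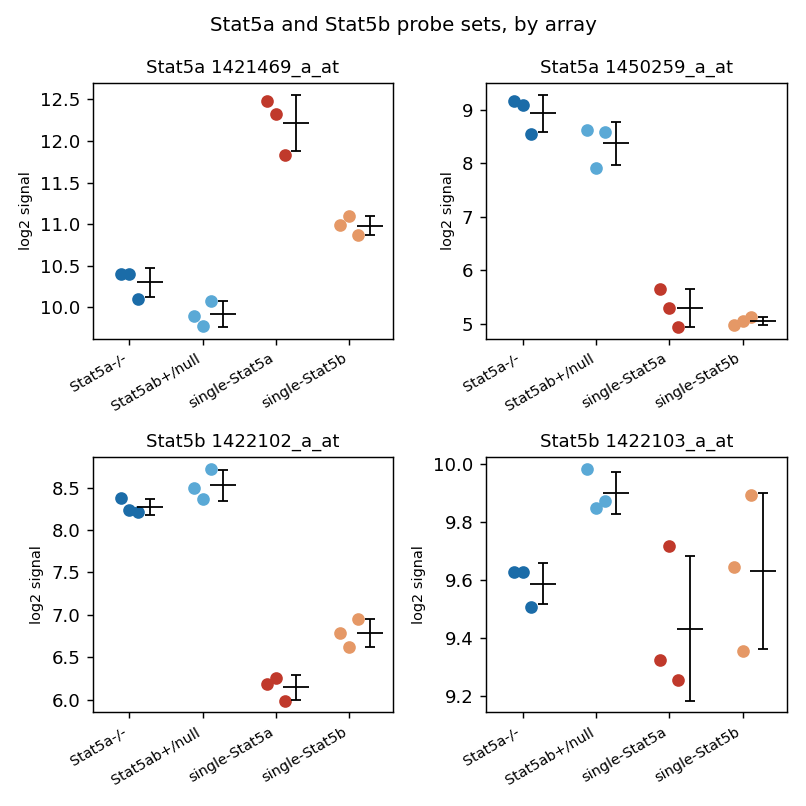
Log2 signal of the 2 Stat5a and 2 Stat5b probe sets by genotype; points are arrays and black lines the mean ± SD (n = 3). Probe sets of 1 gene move apart between the genotypes with 1 intact allele and those with 2. In single-Stat5a against Stat5ab+/null, Stat5a differed by 2.30 on 1 probe set and by -3.08 on the other.

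The arrays fell into 2 sets that follow the total number of intact alleles, with single-Stat5a and single-Stat5b (1 allele) in one and Stat5a-/- and Stat5ab+/null (2 alleles) in the other. Across probe sets, which are not independent replicates, arrays of different sets correlated with a Pearson r of 0.818 to 0.883, arrays of 1 genotype with 0.957 to 0.993, and arrays of the other genotype with the same allele total with 0.949 to 0.994. The first principal component held 75.6% of the variance. Bacterial hybridization controls, which carry no mouse RNA, averaged 11.62 ± 0.03 in Stat5a-/-, 11.96 ± 0.05 in Stat5ab+/null, 12.84 ± 0.05 in single-Stat5a and 13.09 ± 0.34 in single-Stat5b (SD, n = 3). Over all 42 spike-in control probe sets the median difference between the sets was 1.59 on the log2 scale, and 34 differed by more than their range within either set. The 3' minus 5' signal of the actin control, a sign of RNA or labelling quality, was 0.15 ± 0.02 and 0.22 ± 0.04 in Stat5a-/- and Stat5ab+/null against 2.55 ± 0.47 and 2.79 ± 0.87 in single-Stat5a and single-Stat5b. For Gapdh it was -0.04 ± 0.06 and 0.01 ± 0.05 against 1.78 ± 0.89 and 2.17 ± 1.52. The labels name no batch. No genotype has arrays in both sets, so the allele total and the array set cannot be told apart, and comparisons within a set are given first.

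**Figure D2:**
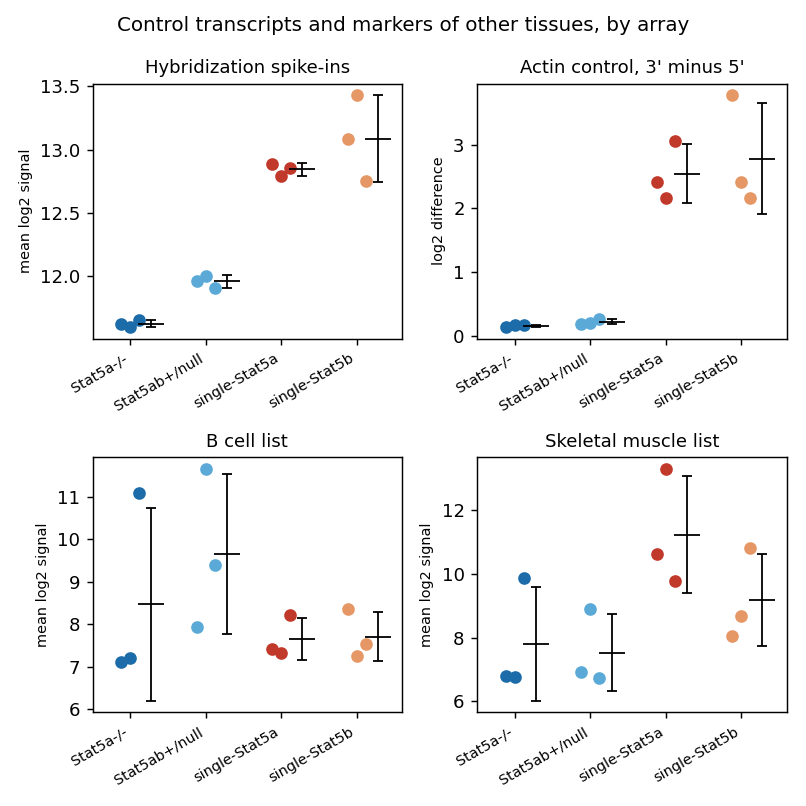
Log2 values per array (points; black lines mean ± SD, n = 3) for the hybridization spike-ins, the actin 3' minus 5' difference, the B cell list mean and the skeletal muscle list mean, by genotype. Spike-ins and the actin difference separate the sets, while B cell and muscle markers stand high in single arrays, such as 13.3 for muscle in single-Stat5a 2.

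Stat5a-/- against Stat5ab+/null sets 2 Stat5b alleles beside 1 allele of each gene at the same allele total. Milk protein transcripts as a group were higher in the arrays labelled Stat5a-/-, with 8 of 11 measured members above 0 and a median log2 difference of 0.34 (camera adjusted p = 1.76e-05). Csn1s1, the alpha-S1 casein gene, stood at 9.93 ± 1.80 against 7.54 ± 0.23 (SD, n = 3), and Csn2, the beta-casein gene, at 6.76 ± 0.53 against 5.10 ± 0.43. The Stat5ab+/null arrays lie under the filter level of log2 6.04 for Csn2, which passed the filter through its signal in the 1-allele arrays (8.58 to 11.3). Cel, the bile-salt-stimulated lipase of milk, stood at 8.30 ± 0.20 against 7.49 ± 0.22, and Csn3, the kappa-casein gene, at 12.06 ± 0.28 against 11.26 ± 0.32. Every array labelled Stat5a-/- lay above every Stat5ab+/null array for these 4 genes. Ido1, which opens the breakdown of tryptophan to kynurenine, fell by 1.81 on the log2 scale (SE 0.20, 3.50-fold lower), from 8.29 ± 0.15 to 6.48 ± 0.12.

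The milk protein call held with an estimated correlation (adjusted p = 0.0179) and not with fry (0.140). Its members differed by 2.39 (SE 0.78) for Csn1s1, 1.66 (SE 0.55) for Csn2, 0.81 (SE 0.26) for Cel, 0.80 (SE 0.28) for Csn3 and -0.94 (SE 1.94) for Glycam1. Without Stat5a-/- 3, Csn1s1 differed by 1.40. Glycam1 stood at 12.16 in Stat5a-/- 3 and 12.54 in Stat5ab+/null 2, the arrays of these groups with the highest B cell list means (11.1 and 11.7), and at 5.39 to 7.77 in the other 4. No milk protein gene passed over all genes (adjusted p = 1.00 each), and 4 of the 11 passed when adjusted over the list alone, all higher. The median was 0.19 without any one of single-Stat5a 1 and 3 and single-Stat5b 1, 2 and 3, 0.08 with no filter on low signal and 0.10 with 4 arrays left out (chosen after seeing the data), with the call kept. The single-Stat5a and single-Stat5b arrays do not enter this difference. Leaving them out moved the median because the filter and the choice of probe sets were redone, which changed the members measured. Secretory differentiation genes were called higher (12 of 15 above 0, median 0.19, adjusted p = 0.00787), with Slc34a2 at 0.45, Gjb2 at 0.42, Muc15 at 0.40 and Elf5, a luminal transcription factor, at 0.34. None of them passed alone or when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.513), fry (0.952) and no filter (0.0526). B cell and plasma cell genes were called lower (0 of 11 above 0, median -1.32, adjusted p = 0.0192, but adjusted p = 0.920 with an estimated correlation and 0.952 with fry), among them Ms4a1 (-2.00), Jchain (-1.59), Cd79a (-1.50) and Mzb1 (-1.44), with none past adjustment over the list alone. The mean signal of this list per array was 7.11, 7.20 and 11.1 in Stat5a-/- 1 to 3 and 7.93, 11.7 and 9.38 in Stat5ab+/null 1 to 3, so that it differs more between mice of 1 genotype than between the genotypes. The B cell call ended without Stat5a-/- 1 (adjusted p = 0.489), Stat5a-/- 2 (0.482), single-Stat5b 2 (0.106) or single-Stat5b 3 (0.0672), and without Stat5ab+/null 2 the test turned to higher (0.876). Of the known Stat5 target list, uncalled here, Wnt4 differed by -0.83, Socs3 by -0.58, Id2 by 0.46 (another probe set -0.085) and Pim1 by -0.43 (another 0.14).

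Over all genes, limma called 1 gene in this comparison, Ido1 (adjusted p = 0.0104, non-overlapping in 3 of 3 arrays per group), while 427 genes had an unadjusted p under 0.05, which is 3.01% of those tested. Groups did not overlap for 19.1% of genes, where chance gives 10%. Ido1 no longer passed without Stat5a-/- 1 (adjusted p = 0.103) or 2 (0.135), or without Stat5ab+/null 1 (0.124), 2 (0.105) or 3 (0.0514), at log2 differences of -1.89 to -1.75 in these 5 runs. The count was 2 without Stat5a-/- 3 or single-Stat5b 2 and 5 without single-Stat5a 2, and it was 202 with array weights.

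**Figure D3:**
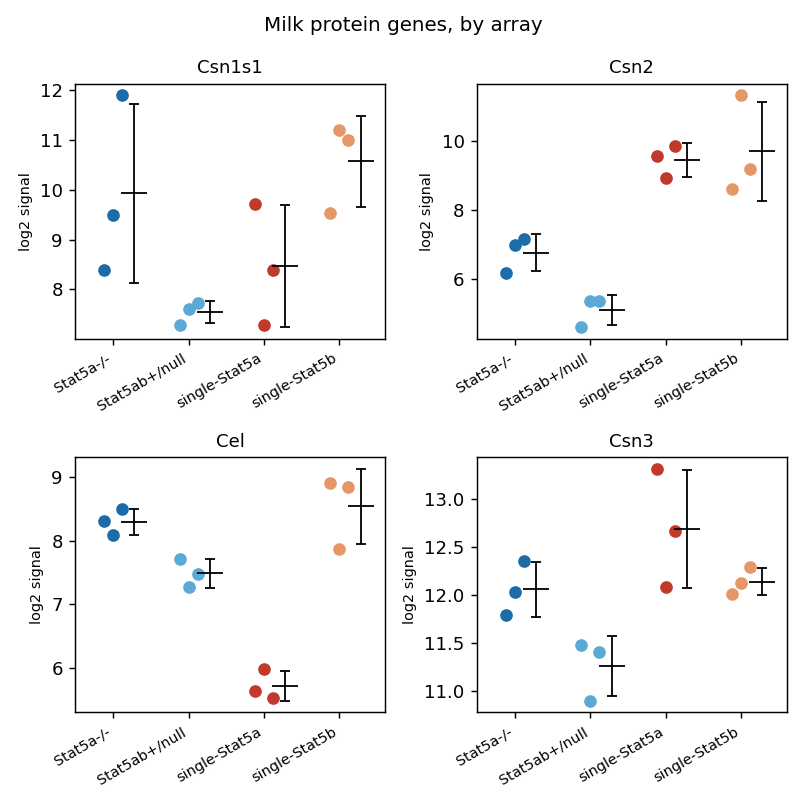
Log2 signal of Csn1s1, Csn2, Cel and Csn3 by genotype; points are arrays and black lines the mean ± SD (n = 3). Each of the 3 arrays labelled Stat5a-/- lies above each Stat5ab+/null array, and Cel is lowest in single-Stat5a at 5.72 ± 0.24.

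Single-Stat5b against single-Stat5a asks which isoform remains as the only intact allele. H2-Ea, the alpha chain of a class II histocompatibility molecule, stood at 13.02 ± 0.29 in single-Stat5b and 5.24 ± 0.72 in single-Stat5a (SD, n = 3; log2 difference 7.78, SE 0.32). Ifi202b, an interferon-induced gene, stood at 11.35 ± 0.44 against 5.60 ± 0.52, and Hal, the enzyme that opens histidine breakdown, at 10.38 ± 0.65 against 5.18 ± 0.28. Cel rose by 2.82 (SE 0.26), from 5.72 ± 0.24 to 8.54 ± 0.59. Xdh, the xanthine dehydrogenase needed to wrap milk fat droplets, fell by 3.27 (SE 0.25), from 11.65 ± 0.13 to 8.38 ± 0.15.

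The adjusted p-values from limma were 1.36e-08 for H2-Ea, 4.27e-08 for Ifi202b, 1.14e-06 for Hal, 3.68e-05 for Cel and 5.87e-06 for Xdh, each with no overlap between the 3 arrays of each group. Background was not measured. Of the genes named in this paragraph and the one before, all but Gbp2b, Rbm45, Tmem87a, Trim34a and Xdh have a group mean under the filter level of log2 6.04. Their differences between these 2 groups are lower bounds if that mean is background. For genes such as Trim12a and H2-Q10, the means in Stat5a-/- and Stat5ab+/null are also under that level, and isoform averages and interactions are then not bounded. Where only the single-Stat5a mean is under it, as for H2-Ea, Ifi202b and Hal, they are lower bounds too. The order of these genes by size is that of the printed values alone. The genotype that stood apart differed by gene. Levels set beside Stat5a-/- and Stat5ab+/null cross the array sets and carry that split too. H2-Ea, Ifi202b and Hal were low in single-Stat5a alone, against 13.49 and 13.46, 11.96 and 12.08, and 11.43 and 11.64 in Stat5a-/- and Stat5ab+/null. Xdh was low in single-Stat5b alone, against 11.72 ± 0.55 and 11.58 ± 0.31. Trim12a (fell by 5.76), Cdsn, the skin adhesion protein corneodesmosin (fell by 6.18), and H2-Q10, a class I histocompatibility gene (fell by 4.82), were high in single-Stat5a alone, at 10.20 ± 0.13, 11.48 ± 0.56 and 10.01 ± 0.33. The other large rises were AI506816 (5.31), Map3k7cl (4.29), the guanylate-binding Gbp2b (4.16), the RNA-binding Rbm45 (3.99), Ifi44l (3.88), the histone gene H2bc18 (3.69) and Tmem87a (3.42). The other large falls were Cep85 (-5.06), Zfp874a (-4.87), Cldn34c1 (-4.84), Phkg1, a subunit of the phosphorylase kinase of muscle (-4.21), Trim34a (-4.18) and Hps1 (-3.95). Probe sets of a gene did not always move together: the remaining ones gave 6.02 and 0.19 for H2-Ea, the latter at a mean signal of 3.52, -0.14 for Trim12a, -0.42 for Cep85, -0.34 for Trim34a and -0.47 to -0.11 for Hps1. Cep85 differed by -0.52 without single-Stat5a 1 (adjusted p = 0.336).

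**Figure D4:**
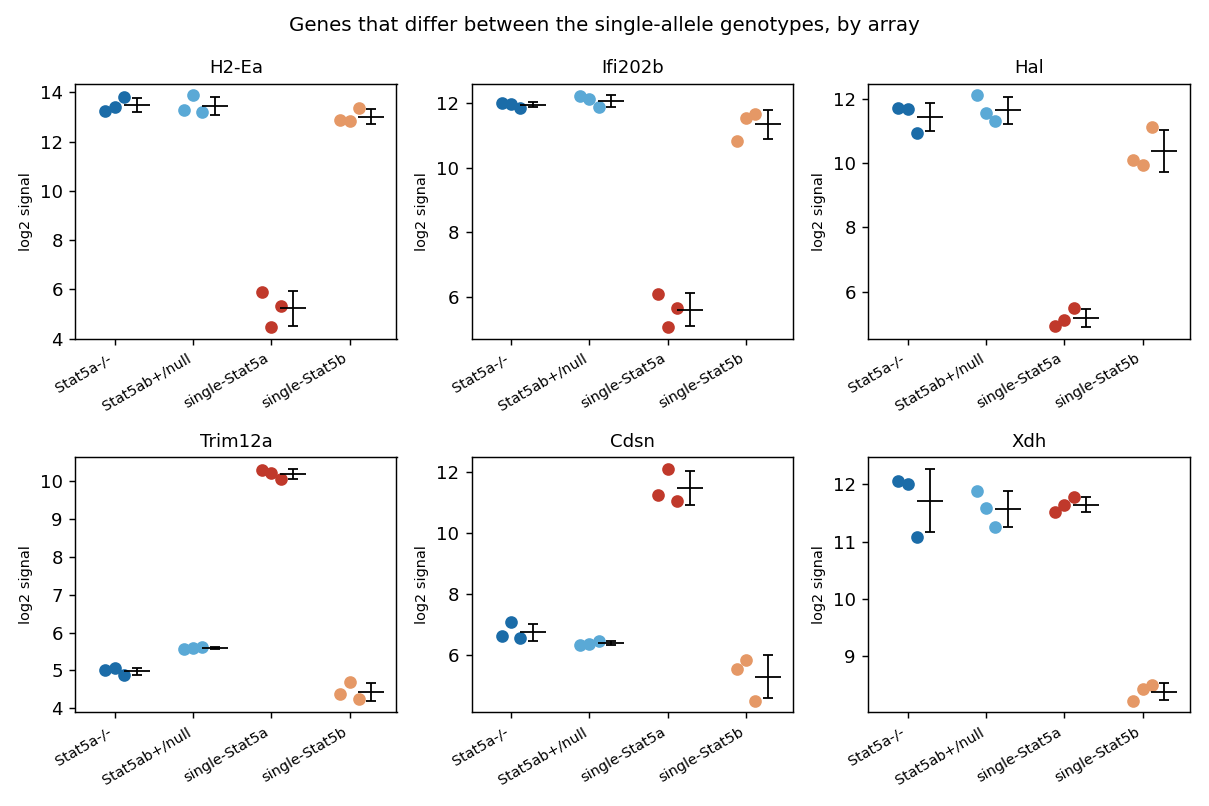
Log2 signal of H2-Ea, Ifi202b, Hal, Trim12a, Cdsn and Xdh by genotype; points are arrays and black lines the mean ± SD (n = 3). The 3 arrays of 1 genotype stand apart from the other 9 for each gene, single-Stat5a for the first 5 and single-Stat5b for Xdh.

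Among gene groups in this comparison, interferon response genes were called lower in single-Stat5b (2 of 17 above 0, median -0.69, camera adjusted p = 5.41e-06), with Rsad2 at -1.37, Ifit3 at -1.27 (adjusted p = 0.00215), Ifit1 at -1.09 and Mx1 at -0.96. Of the 17, 1 fell over all genes and 7 fell when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.587) and with fry (0.0923). Ifi202b, Gbp2b and Ifi44l, which are induced by interferon but were not on the list, moved the other way. Skeletal muscle genes were called lower (0 of 13 above 0, median -2.23, adjusted p = 4.94e-04, and adjusted p = 0.661 with an estimated correlation), with Actn3 and Myh4 both at -3.40, Tnnt3 at -2.57 and Pvalb at -2.46, and 1 fell when adjusted over the list alone. The mean of this list per array was 10.6, 13.3 and 9.78 in single-Stat5a 1 to 3 and 8.05, 8.69 and 10.8 in single-Stat5b 1 to 3. Luminal epithelium genes were called higher (19 of 21 above 0, median 0.32, adjusted p = 0.00105, and adjusted p = 0.588 with an estimated correlation), with Cldn4 at 0.60, Grhl2 at 0.55, Cldn3 at 0.53 and Ovol1 at 0.43 (another probe set -0.31). Hormone-sensing luminal genes were called higher (9 of 12 above 0, median 0.46, adjusted p = 0.00536, and adjusted p = 0.587 with an estimated correlation), with Greb1 at 0.88 (another probe set -0.064), Tbx3 at 0.85 (others -0.099 to 0.31), Tnfsf11 at 0.75 and the progesterone receptor gene Pgr at 0.69. Endothelial genes (2 of 12 above 0, median -0.26, among them Cldn5 at -0.81, Kdr at -0.77, Cdh5 at -0.63 with another probe set at 0.35, and Pecam1 at -0.58) and white adipocyte genes (3 of 16 above 0, median -0.39, among them Lep at -0.99, Plin4 at -0.69, Cidec at -0.67 and Slc2a4 at -0.61) were called lower, each with an adjusted p = 0.0188 and adjusted p = 0.588 with an estimated correlation. Adjusted over the list alone, 1 endothelial gene fell and no luminal, hormone-sensing or adipocyte gene passed, and fry called none of the 6 lists (adjusted p 0.0923 to 0.417). Without single-Stat5a 2, the array with the highest muscle signal, 1 of the 6 calls was left, interferon response, and the other 5 had an adjusted p = 0.146. With the B cell and muscle means as covariates, a choice made after seeing the data, interferon response again was the 1 call of the 6 left (adjusted p = 6.22e-05), and the calls of luminal and hormone-sensing genes (0.188 each), endothelium (0.109), adipocytes (0.158) and muscle (0.911) were lost. The muscle and adipocyte calls also ended without single-Stat5b 1 (0.0510 and 0.0562), the endothelial call without single-Stat5b 2 or 3 (0.0731 and 0.0552), and the adipocyte call without single-Stat5b 2 (0.0731).

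Milk protein genes were not called as a list (7 of 11 above 0, median 0.26, adjusted p = 0.113), with Csn1s1 at 2.11 (adjusted p = 0.274), Glycam1 at 3.17 (0.625; 1.54 without single-Stat5b 1) and Csn1s2a at 0.88 (0.223), and Cel was the 1 member past the test, both over all genes and adjusted over the list alone. Known Stat5 targets were not called either, with Tnfsf11 at 0.75, Igf1 at -0.63 and Wnt4 at 0.54. Igfals, the subunit that carries IGF1 in blood, fell by 1.23 (SE 0.28, adjusted p = 0.0402), and Lpin1, a phosphatidate phosphatase of fat synthesis, fell by 1.04 (SE 0.20, adjusted p = 0.0143). Igfals passed in 11 of 25 alternatives and was lost without any array but Stat5a-/- 2 and single-Stat5b 3 (adjusted p 0.0557 to 0.168). Lpin1 passed in 19 of 25 and was lost without single-Stat5a 2 (0.0628), single-Stat5a 3 (0.0507) or single-Stat5b 1 (0.0639).

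In all, 310 genes differed between single-Stat5b and single-Stat5a (116 higher, 194 lower), 259 of them at least 2-fold and each without overlap between the groups. An unadjusted p under 0.05 was reached by 1641 genes, and groups did not overlap for 10.9% of all genes, where chance gives 10%. The count was 898 without single-Stat5b 3 and 231 to 433 without any other array, 157 in a fit of these 6 arrays alone and 2228 with array weights.

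The isoform average, the mean of those differences, sets the arrays labelled Stat5a-/- and single-Stat5b beside those labelled Stat5ab+/null and single-Stat5a, balanced over the labelled allele total. Milk protein genes were higher in the former (8 of 11 above 0, median 0.17, camera adjusted p = 5.06e-04, but adjusted p = 0.0577 with an estimated correlation), with Csn1s1 at 2.25 (SE 0.55), Cel at 1.82 (SE 0.19), Glycam1 at 1.12 (SE 1.37; 0.0082 without Stat5a-/- 3 and 0.30 without single-Stat5b 1) and Csn2 at 0.96 (SE 0.39). Xdh fell by 1.56 (SE 0.18), and interferon response genes were lower (1 of 17 above 0, median -0.41, adjusted p = 4.67e-05, but adjusted p = 0.613 with an estimated correlation), among them Rsad2 at -0.74, Bst2 at -0.69 and Ifit1 and Mx1 at -0.62. H2-Ea (3.90), AI506816 (3.06), Ifi202b (2.82), Hal (2.50) and Map3k7cl (2.10) had the largest printed rises among called genes, and Trim12a (-3.19), Cdsn (-2.91), Zfp874a (-2.71) and Cldn34c1 (-2.59) the largest falls. In Stat5a-/- minus Stat5ab+/null alone, interferon response was uncalled (median -0.13, camera adjusted p = 0.592). The arrays of these groups overlapped for Xdh, H2-Ea, Ifi202b, Hal, Map3k7cl and Cldn34c1, whose averages therefore rest mainly on the 1-allele groups. Cdsn did not overlap and went against its average. AI506816, Trim12a and Zfp874a did not overlap and went with theirs.

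The milk protein list was also called with fry (0.0185); Cel passed over all genes (adjusted p = 2.20e-04), Csn1s1 did not (0.0912), and 2 members passed adjusted over the list alone, both higher. The list's median was 0.10 without Stat5a-/- 3 or single-Stat5b 3, with the call kept, and Csn1s1 passed without Stat5a-/- 1 (2.64, adjusted p = 0.0346). The interferon list was not called with fry (0.181), and 6 of its genes fell when adjusted over the list alone. Secretory differentiation (median 0.29, adjusted p = 0.0330, but adjusted p = 0.613 with an estimated correlation), endothelium (median -0.22, 0.0368 and 0.753) and luminal epithelium (median 0.14, 0.0445 and 0.986) were called with camera and not with fry (0.933, 0.312 and 0.933). In secretory differentiation, where 11 of 15 were above 0, Gjb2 stood at 0.75, Btn1a1 at 0.59, Muc15 at 0.50 and Slc34a2 at 0.47, and Xdh was the 1 gene that passed, in the other direction. Cldn5 (-0.78), Kdr (-0.50), Cdh5 (-0.40, another probe set 0.090) and Eng (-0.30) led the endothelial genes, of which 2 fell adjusted over the list alone, and Ehf (0.58), Esrp1 (0.27), Cldn4 and Grhl2 (both 0.24) the luminal genes. The secretory call ended without Stat5a-/- 2, Stat5ab+/null 2, single-Stat5a 2 or single-Stat5b 2 or 3 (adjusted p 0.0601 to 0.163). The endothelial call ended without Stat5a-/- 3, Stat5ab+/null 1, single-Stat5a 2 or any single-Stat5b array (0.0509 to 0.136). The luminal call ended without Stat5a-/- 1 or 2, Stat5ab+/null 2 or 3, single-Stat5a 2 or single-Stat5b 1 or 3 (0.0622 to 0.590). With the B cell and muscle covariates the secretory (0.0995) and luminal (0.476) calls were lost, and with the 3' minus 5' covariate the endothelial (0.0723) and luminal (0.0904) calls. In all, 136 genes passed (52 higher, 84 lower), against 1199 at an unadjusted p under 0.05, and the count was 404 without single-Stat5b 3. Of the Stat5 target list, uncalled, Igfals stood at -0.59, Tnfsf11 at 0.58, Socs3 at -0.36 and Bcl6 at 0.36, and Stat5a (-0.42, other probe set 0.16) and Stat5b (-0.06, other 0.19) did not pass.

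The interaction asks whether the exchange of Stat5a for Stat5b differs between a total of 1 and of 2 alleles. These totals are also the 2 array sets, so the allele total and the array set cannot be told apart here either. For Cel the exchange gave 2.82 at 1 allele and 0.81 at 2, an interaction of 2.01 (SE 0.37, adjusted p = 0.0234). H2-Ea (7.76), Ifi202b (5.87), Hal (5.41), AI506816 (4.50) and Gbp2b (4.41) had the largest positive interactions among called genes, and Cdsn (-6.53), Cep85 (-5.51), Trim12a (-5.15) and H2-Q10 (-4.99) the largest negative ones. Xdh (-3.41, adjusted p = 2.36e-04), Stat5a (-1.62, 0.0119) and Ifit3 (-1.41, 0.0277) also passed. Hormone-sensing luminal genes had positive interactions (10 of 12 above 0, median 0.69, camera adjusted p = 9.61e-04, but adjusted p = 0.790 with an estimated correlation), led by Greb1 (1.41), Wnt4 (1.37), Tbx3 (1.36, other probe sets -0.10 to 0.87) and Foxa1 (1.09).

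In camera luminal epithelium (20 of 21 above 0, median 0.42, adjusted p = 0.00138), skeletal muscle (0 of 13, median -2.71, 1.10e-04), interferon response (3 of 17, median -0.41, 4.49e-04) and white adipocyte genes (3 of 16, median -0.40, 0.00731) were called too, each with an adjusted p = 0.790 with an estimated correlation, and fry called none of the 5 lists. Adjusted over the list alone, 4 hormone-sensing genes were higher, 1 interferon gene was lower and no gene of the other lists passed. Muscle markers stood high in single-Stat5a 2 (13.3), and with the B cell and muscle means as covariates, a choice made after seeing the data, the muscle median was 0.09 and interferon response was the 1 call of the 5 left, while hormone-sensing (adjusted p = 0.0766), luminal (0.304), adipocyte (0.291) and muscle (0.808) calls were lost. Ovol1 (0.88, another probe set -0.40), Krt7 (0.83), Cldn3 (0.77) and Cldn4 (0.72) led the luminal genes, Actn3 (-4.09), Myh4 (-3.41), Acta1 (-3.13) and Pvalb (-2.94) the muscle genes, Rsad2 (-1.25), Ifit1 (-0.95) and Irf7 (-0.81) the interferon genes after Ifit3, and Lep (-0.96), Cidec (-0.83), Slc2a4 (-0.81) and Plin4 (-0.61) the adipocyte genes. For milk proteins the list was uncalled with a median of -0.28, which ran from -0.58 to 0.32 with 1 array left out, and a mean of 0.21. Glycam1 stood at 4.11 (0.81 with the B cell and muscle covariates and 2.17 without Stat5ab+/null 2), Csn2 at -1.41 and Csn3 at -1.34. In the Stat5 target list, Igfals stood at -1.27, Igf1 at -0.63 and Pim1 at 0.56 (another probe set -0.32), and Stat5b at 0.51. In all, 110 genes passed (54 higher, 56 lower; 1026 at an unadjusted p under 0.05), with 201 without single-Stat5b 2 and 64 without Stat5a-/- 2. Cep85 differed by -0.38 without single-Stat5a 1. Cel was lost without Stat5a-/- 1 or 2, Stat5ab+/null 1 or 3, single-Stat5a 1 or 3 or single-Stat5b 1 (1.83 to 2.01, adjusted p 0.0620 to 0.0832). Ifit3 was lost without any Stat5a-/- array, Stat5ab+/null 1 or 2, single-Stat5a 2 or 3 or single-Stat5b 1 (-1.47 to -1.27, adjusted p 0.0558 to 0.0992), and Stat5a without Stat5a-/- 2 (-1.57, 0.0541). The luminal call ended without single-Stat5a 2 (0.0515) and the adipocyte call without Stat5ab+/null 2 (0.0519).

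The remaining comparisons cross the array sets: single-Stat5a against Stat5ab+/null (loss of the Stat5b allele), single-Stat5b against Stat5ab+/null (loss of the Stat5a allele), and single-Stat5b against Stat5a-/- (1 against 2 Stat5b alleles). The beta-casein gene Csn2 was higher in the 1-allele arrays in each, by 4.34, 4.59 and 2.93 (SE 0.55), with its other probe set at 0.56, 1.11 and 0.24 and a mean under the filter level in Stat5ab+/null. Bcl6, a transcriptional repressor, was higher by 2.94, 3.47 and 3.30, while its other probe set gave -0.45, -0.35 and -0.26. The cytokine signal inhibitor Socs3 was higher by 2.15, 2.00 and 2.58, while another of its probe sets gave -1.73, -1.83 and -1.56. The tight junction gene Cldn4 fell by 5.57, 4.97 and 4.85, and the ribosomal protein gene Rpl27a rose by 5.85, 5.93 and 5.73, while its other probe set gave 0.16, 0.54 and 0.47. In skeletal muscle, 11 of 13 genes rose in single-Stat5a against Stat5ab+/null, among them Myh4 (5.42), beside list means of 11.23 ± 1.84 and 7.53 ± 1.21 (SD, n = 3).

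Limma called 8373 genes (4505 higher, 3868 lower) in the first of these comparisons, 8542 (4368 higher, 4174 lower) in the next and 8376 (4610 higher, 3766 lower) in the last, and 9007 genes differed among the 4 genotypes by the moderated F test. More genes were lower than higher in each when the arrays were scaled, with 4104 higher and 4326 lower, 4072 and 4510, and 4139 and 4373 after quantile normalization, and 4122 and 4434, 4024 and 4698, and 4155 and 4441 after centring. Camera called no list in the first or the next, where fry called 5 and 6, and lipid synthesis (median -0.58, adjusted p = 0.0345) and white adipocyte genes (median -0.70, 0.0280) as lower in the last, where fry called 5. Both were lost with an estimated correlation (adjusted p = 0.976), quantile normalization (0.142 and 0.119) and the 3' minus 5' covariate (0.0602 and 0.0758). Lipid synthesis was also lost with no filter (0.0565), without Stat5a-/- 2 (0.0588) or single-Stat5b 3 (0.140) and with the B cell and muscle covariates (0.0716). In lipid synthesis 11 of 21 genes fell and 2 rose, and in white adipocyte genes 9 of 16 fell and 0 rose, with the same counts adjusted over the list alone. The examples were the citrate carrier Slc25a1 (-3.00), Gpat4 (-2.27), Dgat1 (-1.95, another probe set 0.71) and Srebf1 (-1.91), and Lipe, a lipase of stored fat (-3.10), Pnpla2 (-2.22, another probe set 2.21), Plin4 (-2.10) and Cidec (-1.71). These values carry both the allele total and the array set, and for 6836 genes with another probe set past the filter, the differences between the sets correlated across genes with a Pearson r of 0.149 and a Spearman rho of 0.133, where genes are not independent replicates. Of 2659 such genes that differed by at least 1 log2 unit on the first probe set, 1137 (42.8%) differed in the opposite direction on the other. The same shares were 22.4% (33 of 147) for single-Stat5b against single-Stat5a and 7.69% (1 of 13) for Stat5a-/- against Stat5ab+/null.

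**Figure D5:**
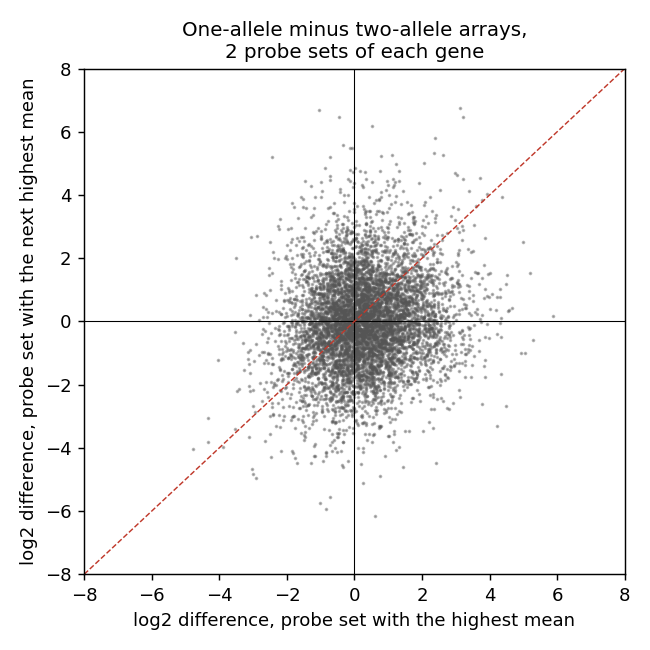
Log2 difference between 1-allele and 2-allele arrays on the probe set with the highest mean signal (x axis) and on the next highest (y axis) for 6836 genes (points); the dashed line marks equal differences. The points do not follow the line (Pearson r 0.149 across genes).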

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

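The interaction and the counts of other splits of the samples were fixed before the data were examined, and the tests of spike-ins, probe sets, allele number, exchanged labels, a single decisive array, the 2 kinds of covariate, the genes next to Stat5a and the make-up of the splits were chosen only after the result was seen. For the exchange of Stat5a for Stat5b, 110 genes had a different effect in the 1-allele and the 2-allele arrays by the limma interaction test. Whether the allele total or the array set lies behind this cannot be told apart. The named ones were H2-Ea (7.76), Ifi202b (5.87), Hal (5.41), AI506816 (4.50), Gbp2b (4.41), Cel (2.01), Ifit3 (-1.41), Stat5a (-1.62), Xdh (-3.41), H2-Q10 (-4.99), Trim12a (-5.15), Cep85 (-5.51) and Cdsn (-6.53). By camera 5 lists also differed, with median interactions of 0.69 for hormone-sensing luminal genes, 0.42 for luminal epithelium, -0.41 for interferon response, -0.40 for white adipocytes and -2.71 for skeletal muscle, all lost with an estimated correlation (adjusted p = 0.790) and all but interferon response with the B cell and muscle means as covariates (adjusted p 0.0766 to 0.808). Of 200 possible regroupings within the array sets, 100 were drawn. Of these, 4, the real one among them, gave as many interaction genes (real split 110, highest other 145). Again with the real one, 3 gave as many isoform average genes (136, highest other 179), and both shares are under 0.05. The other splits as large kept the single-Stat5a and single-Stat5b groups whole, with or without an exchange of their names. Most of them moved arrays within the 2-allele set, so both counts rest on the difference between the 1-allele groups. Those 6 arrays have 10 splits of their own, and the shares fall under 0.05 only through crossing these with regroupings of the 2-allele arrays. Chance is therefore not excluded for the 1-allele groups or for the part of the 2-allele groups. Nor is it excluded for an interaction or an average that needs both. For differences among the 4 genotypes, 1 of 100 regroupings, the real one with 9007 genes, gave as many, and the highest other gave 35. These regroupings moved arrays across the 2 array sets, so that share cannot tell the genotypes from the split between the sets. The comparisons of 6 arrays have 10 splits, too few for a share under 0.05: the real split alone, 1 of 10, gave the most genes for single-Stat5a minus Stat5ab+/null (8373, highest other 0), single-Stat5b minus Stat5ab+/null (8542, 0), single-Stat5b minus single-Stat5a (310, 0) and single-Stat5b minus Stat5a-/- (8376, 0). For Stat5a-/- minus Stat5ab+/null, 2 of 10 splits gave as many as the real 1 gene, and the highest other gave 24. That split sets Stat5a-/- 3 and Stat5ab+/null 2 and 3 apart, the 3 arrays of this set with the highest B cell list means (11.1, 11.7 and 9.38), and points to a structure of these samples other than genotype.

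The arrays split by the total number of intact Stat5 alleles, with 8373 to 8542 genes called across it. The number of intact alleles as the source of the spike-in difference is argued against by the controls themselves, since 34 of 42 spike-in probe sets, which carry no mouse RNA, differed between the sets by more than their range within either. A labelling or hybridization batch is a candidate explanation, with a median spike-in difference of 1.59 on the log2 scale, and so is change at the level of single probes rather than of transcripts, with a correlation across genes of 0.149 between the set differences of probe sets of 1 gene. On the same measure across genes, r was 0.363 for single-Stat5b against single-Stat5a and 0.341 for Stat5a-/- against Stat5ab+/null. Within the 2-allele set, the median r between the probe sets of the 200 most variable genes was 0.923 over 6 arrays. Probe sets of such genes can follow each other, but this value, taken within genes picked for high spread, is not comparable with 0.149. For the mouse genes, the allele number and the array set cannot be told apart, since 0 genotypes have arrays in both sets.

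Single-Stat5b and single-Stat5a differed in 310 genes, among them H2-Ea (log2 difference 7.78), where 1 genotype stood apart from the other 3. Skeletal muscle in the dissection was examined with B cell and muscle means as covariates. The called genes kept a median of 0.979 of their log2 change (quartiles 0.888 and 1.06). Of the 310, 182 stayed past the threshold in a fit with fewer residual degrees of freedom. The called genes were picked for small spread within groups, so a slope fitted within groups can change them little. The ratio therefore does not decide on this cause. For RNA or labelling quality, with the 3' minus 5' signal as covariate, the median ratio was 0.994 (quartiles 0.967 and 1.02) and 276 of 310 were still called. The same limit holds. This signal also differed little between the groups (actin 2.55 ± 0.47 in single-Stat5a and 2.79 ± 0.87 in single-Stat5b), so the ratio could hardly move and does not decide either. Strain or passenger variants carried in chromosomal blocks may account for part of the calls: 21 pairs of called genes were next to each other in gene order, against a median of 6 and an upper end of the 95% range of 12 in 10000 random draws (permutation p = 1e-04, the smallest they can give) and 7 pairs among as many top genes of single-Stat5a minus Stat5ab+/null, and C57BL/6 mice are known to lack expression of H2-Ea and Ifi202b. The draws treat genes as independent, so neighbours that vary together for another reason could also raise the count. The 7 pairs come from a comparison across the array sets, where probe sets of 1 gene often disagree, and are a weak reference. The remaining Stat5 isoform, which the design names, stays open and was not tested apart from strain; within 100 genes on each side of Stat5a, 1 of 199 genes was called (0.503%), against 17 of 999 (1.70%) elsewhere on chromosome 11.

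Milk protein transcripts were higher in the arrays labelled Stat5a-/- than in Stat5ab+/null (median log2 difference 0.34). Lymph node or muscle in the dissection stays open as a cause. With the B cell and muscle means as covariates the median was 0.52, 1.54 times the unadjusted one. Another run, also chosen after seeing the data, left out together an array of each genotype, among them those highest in B cell markers in these groups. There the median fell well below 0.34, with the call kept. The runs moved the median in opposite directions and do not decide on this cause. A single decisive array is argued against for the members measured, with their probe sets held fixed. Without Stat5a-/- 1, the run with the lowest median of the 6 arrays compared (0.23), the median kept 0.692 of its size. An exchange of the labels of the 2 genotypes could also give this direction and stays open: mean Stat5b signal differed by -0.28 (95% interval -0.57 to 0.01, exact permutation p = 0.1, the smallest this design allows), against the allele numbers, and mean Stat5a signal by 0.47 (exact permutation p = 0.2), while the letters in the titles, if they count intact alleles, keep the order of the labels and speak against an exchange. A genotype effect also stays open and untested.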

How the results depend on the processing

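The alternatives with covariates or with 4 arrays left out were chosen only after the result was seen, and the others before the data were examined. Over all alternatives, values of named genes kept their direction and side of the threshold in 10507 runs, lost the call in 305, gained it in 65 and turned in 43, and for lists these numbers were 428, 106, 1 and 11. Cel (2.64 to 3.30) and Xdh (-3.35 to -3.19) kept their calls between single-Stat5b and single-Stat5a under each alternative. The milk protein list in Stat5a-/- minus Stat5ab+/null kept its call under each alternative except fry (medians 0.08 to 0.52). Where no construction is named below, the cause was not tested. Probe sets with a mean signal under log2 6.04, the 30th percentile, were not tested except with no filter, and since background was not measured here, the limit set by signal over background is not known. No paired analysis was possible because the labels link no mice across genotypes and replicate numbers follow only the order of the records. Quantile normalization and centring moved the median of all genes in single-Stat5b minus Stat5a-/- by -0.11 and -0.12, and in no other comparison by more than 0.1. Where an array is left out of a group, its other arrays are assumed to vary like the rest.

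The number of called genes depended on the setting as follows. Testing every probe set, which tests more features, gave 19670 for single-Stat5a minus Stat5ab+/null (8373 before), 19995 for single-Stat5b minus Stat5ab+/null (8542), 19855 for single-Stat5b minus Stat5a-/- (8376), 912 for single-Stat5b minus single-Stat5a (310), 3 for Stat5a-/- minus Stat5ab+/null (1), 345 for the interaction (110), 436 for the isoform average (136) and 21088 for the F test (9007). Array weights gave 2228 for single-Stat5b minus single-Stat5a, 202 for Stat5a-/- minus Stat5ab+/null, 1580 for the interaction and 1491 for the isoform average. No moderation gave 0 for Stat5a-/- minus Stat5ab+/null, 68 for the interaction and 90 for the isoform average. Fits of only the groups compared, with fewer arrays, gave 157 for single-Stat5b minus single-Stat5a and 2 for Stat5a-/- minus Stat5ab+/null. An adjusted p under 0.01, stricter by construction, gave 188, 0, 59 and 84 for single-Stat5b minus single-Stat5a, Stat5a-/- minus Stat5ab+/null, the interaction and the isoform average. A filter at the 50th percentile gave 0 for Stat5a-/- minus Stat5ab+/null. With the B cell and muscle covariates the counts were 4503 for single-Stat5a minus Stat5ab+/null, 3 for Stat5a-/- minus Stat5ab+/null and 66 for the interaction. With the 3' minus 5' covariate they were 4969 for single-Stat5b minus Stat5ab+/null, 4801 for single-Stat5b minus Stat5a-/- and 4300 for the F test. With 4 arrays left out they were 0 for Stat5a-/- minus Stat5ab+/null and 79 for the isoform average. With 1 array left out the counts were 0 to 5 for Stat5a-/- minus Stat5ab+/null, 231 to 898 for single-Stat5b minus single-Stat5a, 64 to 201 for the interaction and 96 to 404 for the isoform average. The highest came without single-Stat5a 2, single-Stat5b 3, single-Stat5b 2 and single-Stat5b 3, and Stat5a-/- 2 gave the 64.

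The number of called lists also moved. For Stat5a-/- minus Stat5ab+/null (3) it was 1 with an estimated correlation, 0 with fry, 6 with 4 arrays left out and 2 to 7 with 1 array left out. For single-Stat5b minus single-Stat5a (6) it was 0, 0, 2 and 1 to 8 in the same order, with 1 without single-Stat5a 2, and 3 (0 higher, 3 lower) with the marker covariates. For the interaction (5) it was 0 with an estimated correlation and with fry and 4 to 9 with 1 array left out, and 4 (0 higher, 4 lower) with the marker covariates. For the isoform average (5) it was 0, 1, 3 and 2 to 7 in the first order, and 3 with the 3' minus 5' covariate. For single-Stat5a minus Stat5ab+/null (0) it was 3 with the mean of probe sets, 5 with fry, 1 with 4 arrays left out, 1 with the 3' minus 5' covariate and 0 to 1 with 1 array left out. For single-Stat5b minus Stat5ab+/null (0) it was 3, 6, 1, 1 and 0 to 1 in that order, and 1 with the marker covariates. For single-Stat5b minus Stat5a-/- (2) it was 1 with no filter, 0 with quantile normalization, 0 with an estimated correlation, 5 with fry, 1 with the marker covariates, 0 with the 3' minus 5' covariate and 1 to 3 with 1 array left out.

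Directions turned in these cases. With the mean of a gene's probe sets, which averages probe sets that move apart, single-Stat5a minus Stat5ab+/null gave Stat5a -0.39, Dcn 0.37 and Pnpla2 0.43. Single-Stat5b minus Stat5ab+/null gave Flt1 -0.15, Stat5a -1.13 and Dcn 0.63. Single-Stat5b minus Stat5a-/- gave Grhl2 -0.024, Flt1 -0.090, Stat5a -1.60, Stat5b -0.72, Dcn 0.68 and Loxl1 0.0082, and the isoform average gave Stat5b 0.068. The milk protein list in the interaction kept its median of -0.28 with the mean of probe sets and with fry while its test turned. Stat5b in single-Stat5b minus Stat5a-/- was -0.16 with quantile normalization, -0.078 with centring and -0.15 with the marker covariates. Those covariates also gave Glycam1 2.13 in single-Stat5a minus Stat5ab+/null, Tnnt3 and the muscle list 0.0019 in single-Stat5b minus single-Stat5a, Pim1 0.00029, Glycam1 1.55 and Jchain 0.18 in Stat5a-/- minus Stat5ab+/null with the test of the B cell list (median -0.040) turned, and Pim1 -0.34 and Plin4 0.10 in the interaction; the muscle and B cell lists are the covariates themselves. With 4 arrays left out, Tnfsf11 was -0.10 and Grhl2 -0.053 in single-Stat5b minus single-Stat5a, Plin4 0.028 in the interaction, and Grhl2 -0.020 and Stat5b 0.089 in the isoform average. With the 3' minus 5' covariate Glycam1 was -4.01 in single-Stat5b minus Stat5a-/-. With 1 array left out, Glycam1 ranged from -3.15 to 1.00 in Stat5a-/- minus Stat5ab+/null and from -0.66 to 3.18 in single-Stat5b minus Stat5a-/-, where Csn1s1 ranged from -0.13 to 1.63, Stat5b from -0.087 to 0.18 and the milk protein median from -0.17 to 0.23. Stat5b ranged from -0.12 to 0.014 in the isoform average, the milk protein median from -0.58 to 0.32 in the interaction and the B cell median from -2.62 to -0.19 in Stat5a-/- minus Stat5ab+/null. Esrp2 in single-Stat5a minus Stat5ab+/null ranged from -0.33 to 5.86, since its probe sets, with differences of 5.75 and -0.24, have similar mean signals and leaving out an array changes which is used.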

Other observations

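All tests in this part use lists fixed before the data were examined, and Kit and the chromosomes named were singled out only after the result was seen. Of the 21 lists tested, 12 were called in none of 4 comparisons, those within an array set, the interaction and the isoform average. Genes of the mammary epithelium outside the groups above showed small medians, given first for single-Stat5b minus single-Stat5a and then for Stat5a-/- minus Stat5ab+/null. Alveolar luminal progenitor genes stood at -0.23 and 0.04 (smallest adjusted p = 0.0834), and in the latter comparison Kit was the 1 member that passed adjusted over the list alone, at 0.83. Basal and myoepithelial genes stood at -0.04 and 0.05 (0.119), lipid synthesis genes at -0.04 and 0.04 (0.0509) and known Stat5 targets at -0.10 and -0.03 (0.596). Cell cycle genes stood at 0.03 and -0.14 (0.490).

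The stromal and blood-derived lists were also uncalled there. Medians were -0.38 and -0.10 for brown adipocytes (0.300), -0.04 and -0.04 for fibroblast matrix (0.695), -0.17 and -0.08 for macrophages (0.515), 0.17 and -0.43 for T cells (0.511) and -0.10 and 0.03 for nerve (0.743). Circadian clock genes stood at -0.13 and -0.07 (0.313) and immediate early genes, which respond to handling of tissue, at 0.04 and -0.21 (0.490). The test pointed up where the median was below 0 for basal genes in the first comparison and for brown adipocyte, fibroblast and circadian genes in the other, where the mean of the nerve list was -0.03. The share of tested genes called between single-Stat5b and single-Stat5a was 4.18% (20 of 478) on chromosome 14 and 3.95% (27 of 684) on chromosome 17, which holds H2-Ea, H2-Q10, Cdsn and Xdh. Over all genes with a position, 308 of 14130 were called. These chromosomes were picked for the highest shares, and their excess was not tested.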
